A study of Mus musculus with 8 samples.

How the data were processed

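Genomic DNA from the livers of 8 mice aged 12 months was compared by array comparative genomic hybridisation (array CGH), in which 2 differently labelled DNA samples compete for the same oligonucleotide probes and the ratio of the dyes at a probe reads relative DNA copy number. Of the 8 arrays, 5 carried DNA from hepatocellular carcinomas (HCC, the main primary cancer of the liver) of mice whose hepatocytes lacked Mcl-1, and 3 carried liver DNA of healthy mice with the Albumin-Cre transgene alone. Mcl1 encodes an anti-apoptotic member of the Bcl-2 family. The strain label names a genetic background for the control mice, but only the knock-out for the HCC mice. No normal liver of the tumour-bearing mice was among the arrays. An inherited difference between the mice therefore cannot be separated from a change acquired in the tumours. This holds for HCC against control and for HCC against the pool. Each animal's DNA was hybridised with DNA from pooled control livers. Per the labels' protocols, DNA was purified on columns, fragmented by heat and labelled with an Agilent CGH kit protocol meant for archived tissue, with Cy3 for the individual animal and Cy5 for the pool on every array. No dye swap was recorded, so a dye effect cannot be separated from a difference between animal and pool, but it is common to both groups and cancels in their difference. The labels call the pool on HCC arrays diseased in 1 field and a control pool in others. It was taken as the control pool.

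The deposited table holds 1 log ratio per probe and array for 42404 probes, with no missing value, read here as log2. Of these values 87 are exactly 0, at 52 probes, 41 of them in control 1, and 1 probe is 0 on every array, so they may be placeholders. They were kept, and counts were repeated without those 52 probes. The log base, the direction of the ratio, the background correction, the within-array normalisation and the centring are not given in the sources used here. Base 2 was taken because base 10 would put the largest values beyond the range of a 16-bit scanner, and natural logarithms were not excluded. The deposited column medians lay between -0.00049 (HCC 2) and 0.054 (HCC 1). Correlations between all 28 pairs of arrays were positive (0.035 to 0.413), so no array ran against the others. All signs below are those of the deposited values, and "higher" and "lower" refer to the log ratio, not to gain or loss of DNA. For DNA labelled as described, a Cy5 over Cy3 ratio would be high where the animal has lost DNA. Intensities, and with them the signal over background, were not analysed here. The number of arrays limits the precision.

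No table pairing the probes with genes or positions was used here. Correlations between probes with neighbouring ID numbers lay between -0.012 and 0.003 in the 8 arrays, so the ID order carried no sign of genome order. The planned tests of genes, gene lists, windows, chromosomes, altered autosomal share and recurrent windows therefore were not run, and Mcl1 itself was not read. Probes are named by ID. The tests against the pool used probes in place of windows, as planned for that case.

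Each array was centred on its median over all probes. HCC and control arrays were compared probe by probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p under 0.05) over all 8 arrays, and each group's mean was tested against 0 in a fit of the same arrays. Summaries of each array and correlations between arrays were compared with exact permutation tests over the 56 ways to split 8 arrays into 5 and 3 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1), whose smallest possible p is 0.018. Over 6 tests that p adjusts to 0.107 for a measure that stands alone. The tests of differences were 2-sided and that of the correlations 1-sided. These 6 summary tests replaced the altered share and were chosen after the data were seen, because the probes had no positions here. Each slide held too few arrays to repeat them within it. The labels call the tumours independent, and p-values for controls rest on 3 animals.

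The rule for named probes, fixed before the data were examined, took up to 12 probes per direction with adjusted p under 0.05 and all HCC arrays beyond all control arrays, or the 6 with the smallest p where none passed. Because the probes have no gene names here, the 5 lower probes after the first are summarised without IDs. The alternatives planned were uncentred values, quantile normalisation, a trended robust prior (statmod 1.5.0), slide as a fixed or random block, each of the 2 slides alone, arrays scaled to equal MAD, removal of the noisiest 10% of probes and leaving out each array. Slide 1 held control 1, control 2, HCC 1 and HCC 2, and slide 2 held control 3, HCC 3, HCC 4 and HCC 5. Replicates were numbered in accession order, which pairs no arrays.

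The limma fit was tested on simulated data with the real probe means and spreads, and with residuals shuffled over probes in each array. Of 200 probes shifted in all 5 HCC arrays it recovered 0% at a shift of 0.3 on the log2 scale, 1% at 0.58 and 79.5% at 1, with 2, 1 and 19 false calls. With no shift it made 1 false call, and 5.81% of unchanged probes had an unadjusted p under 0.05. When 4240 probes, drawn at random like the 200, were shifted upward by 0.58 it recovered 1040 of them, with 87 false calls.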

Results

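DNA copy number was probed in liver DNA of 5 tumour-bearing mice with hepatocyte-specific loss of Mcl-1 and of 3 healthy control mice, each against a pool of control liver DNA. The arrays are called HCC 1 to 5 and control 1 to 3. Each array gave a log2 ratio for 42404 probes, and the SD of these ratios over an array was 0.329 ± 0.037 (SD, n = 5) for HCC and 0.343 ± 0.021 (SD, n = 3) for control.

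The first comparison asked which probes differed between tumour DNA and control liver DNA. A single probe, A_53_P113913, passed the test. It averaged 4.0 ± 0.57 (SD, n = 5) in HCC and 0.10 ± 0.12 (SD, n = 3) in control on the log2 scale. The difference was 3.89 with a standard error of 0.27 and a 95% interval of 3.32 to 4.47 (limma, adjusted p = 5.9e-05). If the values are in base 2, this is a 14.9-fold change in the dye ratio (95% interval 9.98 to 22.1). All 5 HCC arrays lay above all 3 control arrays. The lowest HCC value was 3.09 in HCC 2 and the highest control value was 0.23 in control 1. The difference was 3.72 on slide 1 and 4.08 on slide 2. With slide as a block it was 3.88 (limma, adjusted p = 0.00017). On slide 1 alone, with 2 arrays per group, it did not pass (limma, adjusted p = 0.25), where the adjusted p over all 20 alternative fits ran from 7.6e-07 to 0.25.

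No probe passed in the lower direction, where the smallest adjusted p from limma was 0.54. That value belonged to A_53_P144238, which averaged -0.87 ± 0.29 (SD, n = 5) in HCC and 0.27 ± 0.04 (SD, n = 3) in control. Its difference was -1.13 with a 95% interval of -1.52 to -0.74, and the 5 HCC arrays again lay beyond the control arrays. The next 5 probes in that direction differed by -0.87 to -2.34, with limma adjusted p between 0.63 and 0.71. A_53_P144238 passed in 2 alternative fits, once without the noisiest 10% of probes (limma, adjusted p = 0.0060) and once without HCC 2 and control 3 (limma, adjusted p = 0.040). The first fit drops probes by the spread that enters the test, which raises the statistics of the probes kept. In the second the groups coincide with a split of the arrays across the labels, described below. In the 19 alternative fits where A_53_P144238 did not pass, the adjusted p from limma ran from 0.12 to 0.93. Over all 21 the adjusted p from limma ran from 0.0060 to 0.93.

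**Figure D1:**
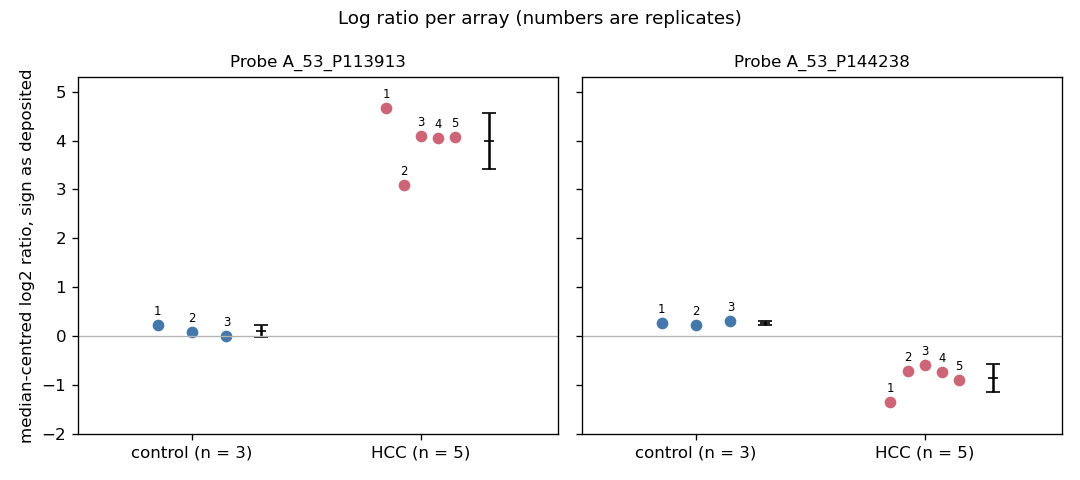
Median-centred log2 ratio (vertical axis, sign as deposited) of the probe that passed the test, A_53_P113913, and of the lower probe with the smallest p, A_53_P144238, in the 3 control and 5 HCC arrays. Points are arrays numbered by replicate, and the bar beside each group is its mean ± SD. At A_53_P113913 the HCC arrays lie between 3.09 and 4.66 and the control arrays between -0.01 and 0.23.

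Shifts of that size were not seen at other probes. Only at A_53_P113913 did every HCC array lie 2 or more above every control array, and no probe (0 of 42404) lay 2 or more below. At a distance of 1 the counts were 1 probe above and 1 below. Across all probes, 2658 (6.27%) had an unadjusted limma p under 0.05, and 1825 (4.30%) had non-overlapping groups, where chance gives 3.57%. Simulated data with no change gave 1 call and 5.81% of probes with an unadjusted p under 0.05. The 95% interval of the difference had a median half-width of 0.39. For 58.3% of probes it lay wholly within ± 0.58, the log2 ratio of 3 copies to 2 in a pure diploid sample, so a mean difference of that size lay outside the interval at those probes if the values are in base 2. When 10% of probes were shifted by 0.58 in all HCC arrays in simulated data, 1040 probes were recovered, against the 1 called in the real arrays. When only 200 probes were shifted by 0.58, 1% of them were recovered, so such a shift at few probes would mostly be missed. In both simulations the shifted probes were drawn at random, so no region of neighbouring probes was simulated. Every simulated HCC array received the full shift. Residuals were shuffled over probes separately in each array, so the structure that groups the real arrays across the labels was absent. The contrast of 1040 with 1 therefore does not exclude a broad shared change.

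The count of called probes stayed at 1 in 15 of 21 alternative fits. It rose to 306 (16 higher and 290 lower) when HCC 2 and control 3 were left out, a choice made after their correlations had been seen. The HCC and control arrays then left lie on opposite sides of a split that crosses the study's groups. That split, control 1, control 2 and HCC 2 against the rest, called 662 probes, 648 of them lower in the rest. The 306 calls therefore cannot be told apart from that structure. Leaving out control 3 alone gave 5 calls, leaving out HCC 2 alone gave 2, slide 2 alone gave 2, removing the noisiest 10% of probes gave 9, and slide 1 alone gave 0 with 1943 probes at an unadjusted p under 0.05.

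The second comparison set each group against the pool. In HCC, 535 probes departed from 0 in limma (88 higher and 447 lower), with a median absolute log2 ratio of 0.56. Without centring there were 412 such probes, 132 higher and 280 lower, and after quantile normalisation 799, 185 higher and 614 lower. In control arrays 0 probes passed, while 4803 had an unadjusted p under 0.05, against 8796 in HCC. Of the 535 probes, 529 had the same sign in all 5 HCC arrays, which follows largely from calling them on the mean of those arrays. In the control mean, 479 (89.5%) had the sign of the HCC mean, where all probes together gave 63.8%. All probes are not a matched baseline, because the 535 were picked for HCC means far from 0 relative to their spread. The control mean at the 535 probes had a median of 0.27 in the HCC direction. Both groups were read against the same kind of pool with the same dyes.

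The HCC count depended on the number of arrays, on which arrays were used and on the prior. With 3 HCC arrays in place of 5, as many as there are controls, the 10 possible sets gave 3 to 56 calls with a median of 5. Sets with HCC 2 gave 3 to 5 calls, and those without it gave 6 to 56. Leaving out HCC 3 gave 12 calls, HCC 1 gave 43, HCC 5 gave 62 and HCC 4 gave 109, but leaving out HCC 2 gave 378. A trended robust prior gave 1.

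The third comparison asked whether tumour arrays were more widely spread than control arrays, as private copy number changes of single tumours would make them. They were not detectably wider, but a measure that stood alone could not have passed, since its smallest possible adjusted p was 0.107. The size of private change that the test could detect was not estimated. The SD of log ratios differed by -0.014 (exact permutation test, p = 0.59, adjusted p = 0.91). It was -0.030 without HCC 5 (exact permutation test, adjusted p = 0.17) and -0.0024 without control 1 (exact permutation test, adjusted p = 0.95). The adjusted p over 9 alternatives ran from 0.17 to 1.0. The widest array was HCC 5 at 0.395, and the other 4 HCC arrays lay between 0.307 and 0.321. Probes at or above 1 made up 0.155% ± 0.144 (SD, n = 5) of HCC arrays and 0.395% ± 0.235 (SD, n = 3) of control arrays (exact permutation test, p = 0.14, adjusted p = 0.43). Probes at or below -1 made up 0.765% ± 0.361 (SD, n = 5) and 0.814% ± 0.297 (SD, n = 3), with exact permutation p = 0.86 and adjusted p = 0.91. The MAD and the skewness differed by -0.0031 and -0.038, each with exact permutation p = 0.91 and adjusted p = 0.91.

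Extreme values confined to 1 array were few. Probes at or above 2.5 in an array and below 1 in the other 7 numbered 9 in HCC 5, 5 in control 2, 4 in HCC 1, 2 in HCC 2, 1 in control 1 and 0 in control 3, HCC 3 and HCC 4. The highest of them reached 5.76 in HCC 1 and 4.16 in HCC 5, against 2.83 in control 2. Probes at or below -2.5 in an array and above -1 in the other 7 numbered 2 in control 3, 1 in HCC 1, 1 in HCC 5 and 0 in the other arrays.

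The last comparison asked whether arrays of a group resembled one another. Pearson's r across probes, which are not independent replicates, averaged 0.261 over the 10 pairs of HCC arrays, 0.083 over the 3 pairs of control arrays and 0.150 over the 15 mixed pairs. The mean within groups exceeded the mean between groups by 0.070 (1-sided exact permutation test, p = 0.036, adjusted p = 0.21 over 6 tests), so the excess did not pass after correction. With 6 tests a single measure could not have passed, since the smallest p of 0.018 adjusts to 0.107 unless other measures are as extreme. It was 0.031 without HCC 3, 0.034 without HCC 1, 0.037 without HCC 4, 0.108 without HCC 2 and 0.136 without control 3. HCC 1, 3, 4 and 5 correlated with one another at 0.282 to 0.413. HCC 2 correlated with them at 0.133 to 0.164 and with control 2 at 0.252. Control 3 correlated with HCC 1, 3 and 4 at 0.266 to 0.273 and with the other controls at 0.035 and 0.064.

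**Figure D2:**
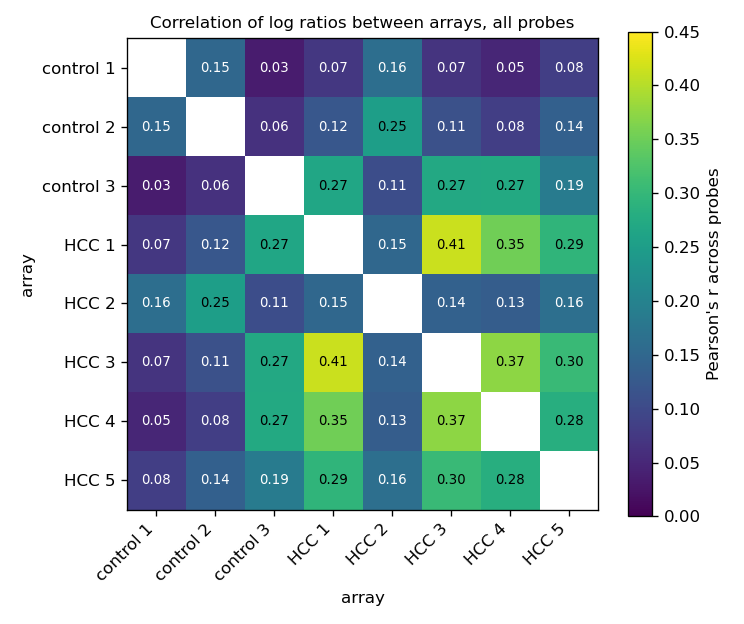
Pearson's r of median-centred log2 ratios between each pair of the 8 arrays (both axes, arrays by group and replicate) across 42404 probes, on a colour scale from 0 to 0.45. The highest value is 0.41 between HCC 1 and HCC 3. HCC 2 has its highest value, 0.25, with control 2.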

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

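The tests of other splits of the arrays, of an exchange of labels, of the slide and of a block of probes in this part were chosen after the result was seen. Of the 11 values checked for outliers, 3 stood apart in the HCC group by Dixon's criterion, which flags about 1 group in 20 by chance. HCC 5 had an SD of log ratios of 0.395 against 0.307 to 0.321 in the other 4 HCC arrays. Its MAD was 0.364 against 0.276 to 0.287. The SD and the MAD both read the spread of that array, so these 2 flags are not separate. HCC 2 had a mean correlation with the other HCC arrays of 0.147 against 0.261 to 0.308. The gap over the range was 0.711 for HCC 2, barely above the critical value of 0.71. These mean correlations share pairs of arrays, so the rate of 1 in 20 need not hold for them.

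The low correlation of HCC 2 is part of a pattern: the split of the arrays that sets control 1, control 2 and HCC 2 against the other 5 called 662 probes (14 higher and 648 lower in the other 5), which points to a structure of the samples other than the study's groups. An exchange of HCC 2 and control 3 stays open. A_53_P113913, itself picked by the labels, read 3.09 in HCC 2 and -0.01 in control 3 and differed most with the arrays as labelled (3.89). Another probe, A_53_P156783, differed most with those 2 exchanged (3.80 in size), a gap of 0.0907 with a standard error of 0.473 from the spread of both probes. Each probe is the largest of all probes in its own split, and the standard error leaves that choice out. That standard error also treats the 2 probes as independent, although they were read on the same arrays. It rests on unmoderated errors, 0.341 for A_53_P113913, where limma gave 0.27. The gap therefore cannot decide on an exchange. The slide stays open as a part of the cause: those 3 arrays lay on slide 1, and the mean correlation within slides exceeded that between slides by 0.0605, which 3 of the 35 splits into 4 and 4 reached (0.104 the highest of the others), but HCC 1, the other array of slide 1, correlated with them at 0.072, 0.123 and 0.150 and with the 4 arrays of slide 2 at 0.266 to 0.413, and limma estimated a correlation of -0.0965 between arrays of a slide. A block of probes that differs in dosage between animals also stays open: 835 probes chosen in the control arrays alone, where controls 1 and 2 exceeded control 3 by 0.8 or more, had medians of -0.40, 0.28, -0.48, -0.43 and -0.22 in HCC 1 to 5, so HCC 2 exceeded the highest other HCC array by 0.503, against 0.012 for the 291 probes chosen in the opposite direction. A candidate explanation is a sex chromosome, which the labels do not allow to be tested because they give no sex and the probes have no positions here.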

How the results depend on the processing

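These alternatives were chosen in advance, except the array weights, the covariate, the fits without HCC 2 and control 3 and without probes with a value of exactly 0, and all alternatives of the array summaries, which were chosen after seeing the data. The difference at A_53_P113913 kept its direction in 20 alternatives (3.47 to 4.12) and its call in 19 (limma adjusted p 7.6e-07 to 0.017). The exception was slide 1 alone. The probe is absent from the fit without the noisiest 10% of probes, which its HCC spread removes. A_53_P144238 kept its direction in 21 alternatives.

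The count of probes called between HCC and control was 1 in 15 alternatives, the same probe each time. It was 0 on slide 1 alone (2 arrays per group), 2 on slide 2 alone, 9 without the noisiest 10% of probes and 306 without HCC 2 and control 3. Leaving out each array gave 1 to 5 calls. The filter on noisy probes uses the spread that enters the test, which raises the statistics of the probes kept. Without HCC 2 and control 3, the groups lie on opposite sides of the split of control 1, control 2 and HCC 2 against the rest. The 306 calls therefore cannot be told apart from that structure. For the other changes the cause was not tested. Calls of HCC against the pool, 535 in the report, were 1 with the trended robust prior and 913 without HCC 2 and control 3, and leaving out each array gave 12 to 683. Calls of control against the pool were 54 without HCC 2 and control 3 and 0 to 5 when each array was left out. The counts of 913 and 54 carry the same limit, since each group then holds arrays from only 1 side of that split. The alternatives for genes, lists, windows, chromosomes, autosomes and GC content were not run, since probes had no positions or names here. No paired analysis was possible because the replicate numbers come from accession order.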

Other observations

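The counts of splits, the block of probes, the covariate, the count of probes with shared large shifts and the sets of 3 HCC arrays in this part were chosen after the results were seen.

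A pair of probes fell into 2 clusters of arrays that cross the study's groups. A_53_P169408 read -0.22, -0.48 and 2.61 in controls 1 to 3 and 3.49, -0.56, 3.12, 2.89 and 2.80 in HCC 1 to 5. A_53_P156783 ran the other way, at 2.98, 2.71 and -1.08 in controls 1 to 3 and -1.54, 1.63, -1.25, -1.62 and -1.32 in HCC 1 to 5. Both were picked for this behaviour. A large set of probes that moves one way by a modest amount, with a probe that moves far in the other direction, is what an X and a Y chromosome could give if the animals differed in sex. A_53_P156783 moved in the direction of the large set by far more than 1 copy against 2 would give, so this account leaves that probe out. The block seen in probes chosen from control arrays (HCC 2 above the highest other HCC array by 0.503) goes with that hypothesis and does not identify the chromosome. With the log ratio of A_53_P169408 as a covariate, the comparison of HCC with control still called 1 probe, the same one as without it. Probes with an unadjusted limma p under 0.05 numbered 2087 with that covariate, against 2658 in the main fit. They numbered 2222 with slide as a fixed block and 2684 with slide as a random block.

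The difference at A_53_P113913 was the largest of any probe in any of the 56 splits of the arrays into 5 and 3. Only 1 split, the real one, reached its 3.89, and the highest in the others was 3.80, a share of 1.79% with no correction for the 4 counts of splits. That is the smallest share the 56 splits can give, so chance is only weakly argued against by this count. The 3.80 belongs to another probe, A_53_P156783, in the split with HCC 2 and control 3 exchanged. A_53_P113913 was the only probe (1 of 42404) at which every HCC array lay 2 or more beyond every control array. A short segment changed in every HCC array, such as a targeted deletion, would give that. A longer gained or lost region would move several neighbouring probes, which cannot be identified without positions. The count restates the observation that prompted it, so it does not decide between these. A candidate explanation is that the probe lies in the part of Mcl1 removed by Cre and that the table gives the pool over the animal, since a high value would then mean DNA missing from the tumour. In base 2 the 14.9-fold ratio would also require that nearly all DNA of the HCC samples lacked that part. The probe's gene and the direction of the ratio were not used here, so this was not tested. A high-level gain at 1 probe is not excluded, nor is an inherited difference between the tumour-bearing mice and the control mice.

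The number of called probes says less than its size. Of the 56 splits, 5 called at least the 1 probe of the real split, with 662 the highest of the others, and 3 gave at least its 2658 probes with an unadjusted p under 0.05, with 3696 the highest of the others. Chance cannot be excluded for either count. For the 535 calls of HCC against the pool, 2 of the 56 sets of 5 arrays gave as many, with 1809 the highest of the others, a share of 3.57% with no correction for the 4 counts of splits, so chance is only weakly argued against. The count fell to 1 with a trended robust prior and to 12 without HCC 3. The set with 1809 calls is the one without control 1, control 2 and HCC 2, so the structure across the labels gives a larger count than the study's groups. The contrast between 535 calls in HCC and 0 in control may come in large part from the number of arrays, since sets of 3 HCC arrays gave a median of 5 calls. Which arrays were used mattered too. Leaving out HCC 2 kept 378 calls, against 12 to 109 without another HCC array. Sets of 3 HCC arrays gave 3 to 5 calls with HCC 2 and 6 to 56 without it. In each of the 10 sets, which overlap, HCC still had more calls than control (3 to 56 against 0) and more probes with an unadjusted p under 0.05 (4738 to 6746 against 3901 to 5065). Whether these counts differ was not tested.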
